A study of Mus musculus with 39 samples.

How the data were processed

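Total RNA from islets of 10 groups of mice was labelled with biotin and hybridized by the authors to Affymetrix Mouse Gene 1.0 ST arrays, 39 in all, with 3 biological replicates at pregnancy day 3.5 and 4 in every other group. The deposited values are on a log2 scale and were made by the authors with robust multi-array average (RMA), which corrects background, quantile-normalizes and summarises each probe set, in Affymetrix Expression Console; its version and which arrays were normalized together are not stated. The values carry 1 decimal and none is missing. Groups and replicate numbers were taken from the sample labels, and no array was left out.

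Of the 35556 probe sets, 21789 were annotated with 1 gene symbol, 1621 with several and 12146 with none. For each symbol the probe set with the highest mean over all arrays was kept, which gave 19938 genes, and 999 genes had a choice of more than 1 probe set. Genome positions are those of the RefSeq gene table for GRCm38. No filter on low values was applied. Signal over background limits what can be seen of a dim gene, and no depth in counts applies to arrays.

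Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and tested two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The comparison of Pdx1-creLate with control littermates used those 8 arrays alone. The pregnancy days, mid-pregnancy (mean of days 9.5, 12.5 and 15.5), 10 days post partum and the step across birth used 1 model of the 31 C57bl6/J arrays. The difference between the transgene and the mid-pregnancy effect and the comparison of control littermates with non-pregnant mice used all 39 arrays. Every comparison with non-pregnant mice shares the same 4 arrays. Changes at any day and among days were tested with limma's moderated F-test. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

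Before the data were examined, the groups, comparisons, tests, alternatives, 29 gene lists and the rule for naming genes were fixed. The lists hold 542 members, of which 489 were measured; the others are not analysed here. Each list was tested with limma's camera with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison, and its members were also counted with p adjusted over the list alone. Of 348 list tests 103 were called, and 12 of those calls held with an estimated correlation. Genes were named by size of change among called genes whose groups do not overlap (10 each way for the transgene, mid-pregnancy and post partum comparisons, 5 each way for single days and the step across birth), by the 10 widest ranges of day means, by the 5 largest interactions each way, as up to 4 called members of a list, and as a short set of lactogenic, serotonin, beta-cell and sex-linked genes named whatever their result; the text takes them in order of size and leaves some out. Slc30a8 and Nkx6-1 in the transgene comparison fall outside this rule and were added after their values were seen.

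Overlap of called genes was set against the number expected from independent lists with a one-sided Fisher's exact (hypergeometric) test. Alternatives were leaving out the dimmest 25% of genes, quantile normalization of all arrays, centring on array medians, eBayes with trend and robust, array weights, the mean of a gene's probe sets, all probe sets, each array's acinar marker mean as a covariate, the replicate number as a block, all 39 arrays in 1 model, only the 2 groups compared, and leaving out each array in turn. Array medians carry 1 decimal like the values, so centring on them is no finer than that step, and the balance of small differences can depend on it. Noise within the rounding step and the SD of each array as a covariate were added after the data were seen. The procedure was tested on simulated arrays. They held each gene's real mean, independent random noise of its real spread, and differences put into some genes. At a log2 difference of 1 it recovered 100% of changed genes in the transgene and mid-pregnancy comparisons and 98.8% in the step across birth. At a difference of 0.5 it recovered 65%, 93.8% and 71.2%, and 8.5%, 2.5% and 5.4% of all its calls were genes left unchanged. The simulation held no correlation between genes and no differences in spread between arrays, so these rates need not hold for the real arrays.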

Results

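RNA from isolated mouse islets was measured on 39 Affymetrix Mouse Gene 1.0 ST arrays, with 1 deposited column of log2 values per array. The arrays fell into 10 groups. Islets of Pdx1-creLate mice and of their control littermates came from the same backcross, with 4 arrays each. The labels as used here give no sex for these groups, but their arrays had the low Xist and high Y-linked expression of males. Pdx1-creLate is a Cre driver line for beta cells that is known to carry a human growth hormone minigene in its transgene. The other 8 groups were C57bl6/J mice that were non-pregnant (4 arrays), at pregnancy day 3.5 (3 arrays), at days 6.5, 9.5, 12.5, 15.5 or 18.5 (4 arrays each), or 10 days post partum (4 arrays). The 35556 probe sets had values from 1.7 upward, and the array medians lay between 5.8 and 6.0. Pearson's r between any pair of arrays lay between 0.9728 and 0.9956 across 19938 genes with 1 probe set each, which are not independent replicates. Read depth does not apply to arrays, and the number of arrays limits the precision of every difference given here. The values carry 1 decimal, so a difference between single arrays is known only to that step. A gene is called where the adjusted p of limma was under 0.05 among the 19938 genes tested. Log2 differences carry their standard error (SE), group levels their standard deviation (SD), and n is 4 per group unless stated.

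The comparison of Pdx1-creLate islets with those of control littermates asks what the transgenic line changes in islets without pregnancy. Tph1, the rate-limiting enzyme of serotonin synthesis in peripheral tissues (probe set 10563570, GRCm38 chromosome 7, 46644641 to 46672537), rose by 5.40 ± 0.46 on the log2 scale, which is 42.2-fold (adjusted p = 2.71e-06). Its level was 10.65 ± 0.24 (SD, n = 4) in Pdx1-creLate and 5.25 ± 1.37 in controls. The tight-junction gene Cldn8 (probe set 10440647, chromosome 16, 88560826 to 88563183) rose by 5.35 ± 0.45 (adjusted p = 2.09e-06), and Lrrc55, an accessory subunit of potassium channels (probe set 10484503, chromosome 2, 85188067 to 85198750), rose by 4.80 ± 0.31 (adjusted p = 1.2e-07). The next largest rises were in Fbxw24 (4.80 ± 0.20), Fmo1 (4.10 ± 0.25), Rerg (3.68 ± 0.16), Sftpd (3.58 ± 0.18), the chloride channel Cftr (3.53 ± 0.23), Gbp8 (3.48 ± 0.16) and the mitochondrial carbonic anhydrase Car5b (3.18 ± 0.14). Dapl1 (probe set 10472235, chromosome 2, 59484653 to 59505020) had the largest fall, −3.03 ± 0.10 (adjusted p = 7.11e-10), followed by Ugt2b34 (−2.63 ± 0.13), the opioid precursor Pdyn (−2.18 ± 0.24), Prom1 (−1.90 ± 0.15) and Tat (−1.88 ± 0.19). These 15 genes were named only among called genes with all 4 Pdx1-creLate arrays beyond all 4 control arrays. Of the 1313 called genes 1208 were of that kind.

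Of 20 measured genes of prolactin, growth hormone and STAT5 signalling, 5 rose and 0 fell. Cish rose by 2.35 ± 0.40 (adjusted p = 0.00177) and Socs2 by 2.25 ± 0.18 (adjusted p = 1.67e-06), both feedback inhibitors of cytokine receptors, and Tnfrsf11b, the decoy receptor osteoprotegerin, rose by 3.15 ± 0.15. The list passed camera (adjusted p = 0.0301) but not with an estimated correlation (adjusted p = 0.314). Of 19 serotonin genes 3 rose, namely Tph1, Tph2 (2.75 ± 0.13) and the vesicular monoamine transporter Slc18a1 (0.78 ± 0.12), with adjusted p = 0.0306 for the list and adjusted p = 0.325 with an estimated correlation. Of 28 genes of endoplasmic reticulum stress and protein folding, 8 rose (12 adjusted over the list alone) and 0 fell, with Chac1 at 0.98 ± 0.14, Derl3 at 0.93 ± 0.14, Trib3 at 0.88 ± 0.13 and Edem1 at 0.83 ± 0.09 (list adjusted p = 7.42e-07, and adjusted p = 0.291 with an estimated correlation). Left-out arrays ended the call of the STAT5 list (adjusted p = 0.0515 and 0.0543 without Pdx1-creLate replicates 1 and 2, and 0.0556 without control replicate 2) and of the serotonin list (0.0515 without Pdx1-creLate replicate 1, and 0.0556 and 0.0531 without control replicates 2 and 3). The cell cycle list was not called (adjusted p = 0.567), with 2 of 37 members lower, and the proliferation marker Mki67 had a difference of −0.13 (adjusted p = 0.666).

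Of 20 measured genes of beta-cell identity, 5 fell and 2 rose in Pdx1-creLate islets (11 and 2 adjusted over the list alone), with a median of −0.25. Ucn3, a marker of mature beta cells, fell by 0.93 ± 0.09 (adjusted p = 1.48e-05), the transcription factor Foxa2 had −0.73 ± 0.09 (adjusted p = 0.000107), the glucose transporter Slc2a2 −0.58 ± 0.09 (adjusted p = 0.0012) and the zinc transporter Slc30a8 −0.45 ± 0.09 (adjusted p = 0.00441). The list passed camera with adjusted p = 0.00348, and had adjusted p = 0.291 with an estimated correlation. The fifth gene, the transcription factor Mafa, had −0.38 ± 0.10 (adjusted p = 0.0283), and its call ended without Pdx1-creLate replicate 1 (0.0978), 2 (0.0721) or 3 (0.0547) and without control replicate 1 (0.085), 3 (0.0627) or 4 (0.0787). Ovol2, a transcription factor, had the larger of the 2 rises (0.58 ± 0.10). Ins2 (−0.08, adjusted p = 0.712), Pdx1 (0.05, adjusted p = 0.836) and Nkx6-1 (−0.43, adjusted p = 0.0534) were not called. Of the 4 genes of pancreatic polypeptide cells 3 fell, most of all the transcription factor Etv1 (−1.15 ± 0.14), with adjusted p = 0.00188 for the list and adjusted p = 0.291 with an estimated correlation. The 22 acinar markers, which report exocrine tissue in the preparations, had a median difference of 0.73 with 0 members called (list adjusted p = 7.9e-05, and adjusted p = 0.585 with an estimated correlation), and their mean was 9.11 in Pdx1-creLate and 8.49 in control arrays. The mouse Gh and Prl probe sets gave 0.00 and −0.10 (adjusted p = 1 and 0.664), and the human minigene itself was not analysed here.

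In all, 1313 genes were called between Pdx1-creLate and control islets, 571 higher and 742 lower in Pdx1-creLate, and 199 of them differed at least 2-fold (134 higher and 65 lower). Centring the arrays on their medians, which are known only to 1 decimal, turned the split to 680 higher and 492 lower. Control replicate 4 had Tph1 at 7.3 against 4.5 to 4.6 in the other controls and Cldn8 at 7.9 against 5.1 to 5.3, and without it the differences were 6.08 for Tph1, 6.02 for Cldn8 and 5.23 for Lrrc55. The count was 820 with every probe set tested on its own, 2484 with all 39 arrays in 1 model and 768 with the SD of each array as a covariate, and the call of Cish ended with a trended and robust variance (adjusted p = 0.0723, the highest of 20 alternatives, from 1.24e-07).

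**Figure D1:**
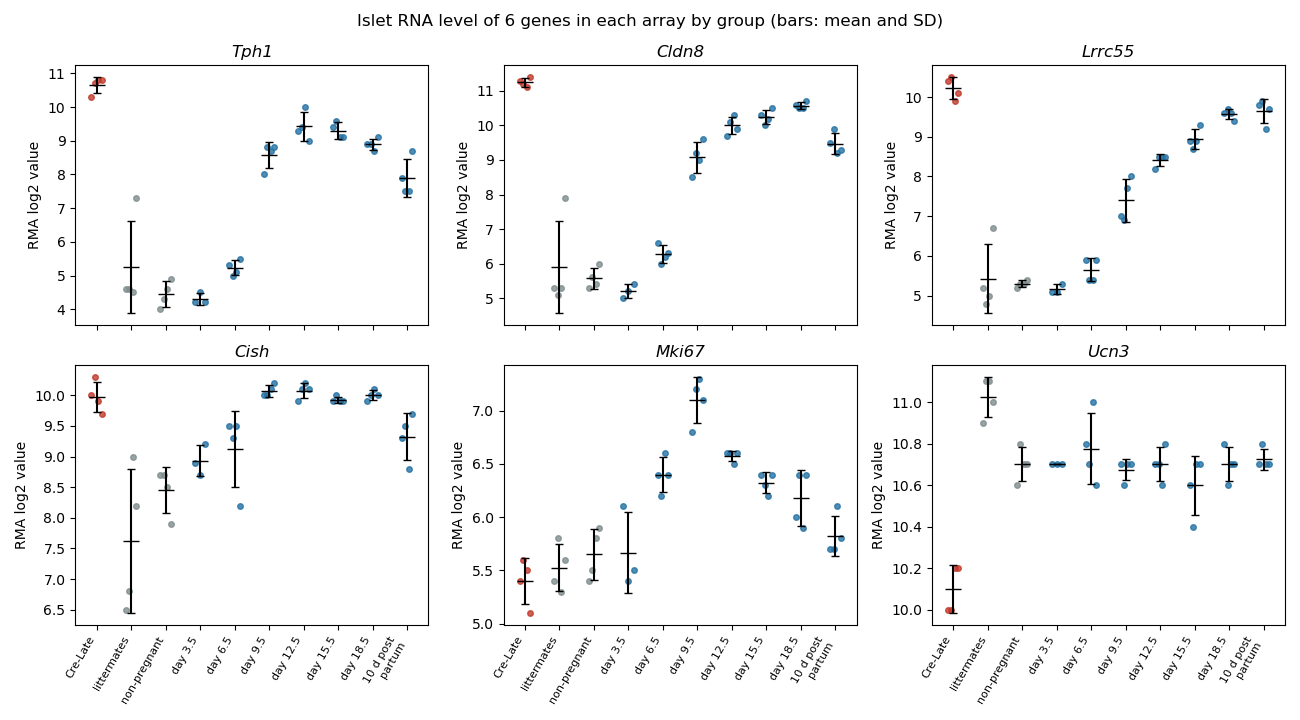
Log2 expression of Tph1, Cldn8, Lrrc55, Cish, Mki67 and Ucn3 on each of the 39 arrays by group; points are arrays and bars are group means with SD. Tph1 averaged 10.65 in Pdx1-creLate and 9.43 at pregnancy day 12.5, against 5.25 in control littermates and 4.45 in non-pregnant mice.

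Mid-pregnancy, the mean of days 9.5, 12.5 and 15.5 (12 arrays), was set against the 4 non-pregnant arrays to describe the islet response to pregnancy. Tph1 rose by 4.65 ± 0.18 (adjusted p = 6.16e-19), Cldn8 by 4.2 ± 0.14 (adjusted p = 4.76e-20) and Lrrc55 by 2.96 ± 0.14 (adjusted p = 1.73e-16). The matrix protein Matn2 rose by 2.5 ± 0.10 and Tph2, the second tryptophan hydroxylase, by 2.26 ± 0.11. Ivd, a mitochondrial enzyme of leucine breakdown, rose by 1.96 ± 0.08, Tmem255a by 1.85, Ehhadh, a peroxisomal enzyme of fatty-acid oxidation, by 1.74 ± 0.08, Neb by 1.67 and Tnfrsf11b by 1.65 ± 0.13. Among called genes whose groups do not overlap, falls were smaller (Rgs2, whose groups touch, had −1.77), with −0.92 ± 0.08 for Pcdh15 (adjusted p = 1.63e-10), −0.85 ± 0.10 for the imprinted gene Zim1, −0.74 ± 0.09 for the cholesterol exporter Abca1, −0.72 for the transcription factor Six4 and −0.71 ± 0.08 for Tat. Apart from Rgs2, these genes were named only among called genes with all 12 mid-pregnancy arrays beyond all 4 non-pregnant arrays. Of the 1843 called genes 541 were of that kind.

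The cell cycle list moved most in mid-pregnancy: 33 of 37 members rose and 0 fell, with a median of 0.52 (adjusted p = 3.7e-39, and adjusted p = 0.000279 with an estimated correlation). Top2a rose by 1.46 ± 0.13, Ccna2 by 1.04, Mki67 by 1.02 ± 0.11 and Tpx2 by 0.96. Of 19 serotonin genes 4 rose, which besides both hydroxylases were Slc18a1 (0.49) and the decarboxylase Ddc (0.32), and the list held with an estimated correlation (adjusted p = 0.00109, and 0.0392 estimated). Of 28 genes of endoplasmic reticulum stress and protein folding 15 rose, led by Derl3 (1.11 ± 0.08), Edem1 (0.82) and Sdf2l1 (0.68), with adjusted p = 3.09e-14 and adjusted p = 0.0869 with an estimated correlation. Of 29 genes of oxidative phosphorylation 13 rose, by 0.45 for Ndufa4 and 0.40 for Cox5a, with adjusted p = 1.21e-11 and adjusted p = 0.17 with an estimated correlation. Cish (1.58 ± 0.16), Socs2 (1.12 ± 0.09) and Myc (1.13 ± 0.18) rose, while the STAT5 list was not called (4 higher, 4 lower, adjusted p = 0.701). Circadian clock genes were lower in 3 of 17 cases, among them Cry2 (−0.67, adjusted p = 1.24e-05) and Per1 (−0.44), with adjusted p = 0.00867 for the list and adjusted p = 0.217 with an estimated correlation. Among beta-cell identity genes 5 rose and 2 fell, the list was not called (adjusted p = 0.0862), and Ins2 (0.19, adjusted p = 0.167) and Ucn3 (−0.04) were not called. The call of Mafa (0.36, adjusted p = 0.0163) ended without non-pregnant replicate 2 (0.14), 3 (0.0924) or 4 (0.0633), and that of Pdx1 (0.28, adjusted p = 0.0103) without replicate 2 (0.0582) or 3 (0.0556).

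In mid-pregnancy 1843 genes were called, 1340 higher and 503 lower, and 46 differed at least 2-fold. Quantile normalization of all arrays together changed the split to 1201 higher and 999 lower, centring arrays on their medians to 1493 and 229, and the SD of each array as a covariate to 861 and 813.

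Each pregnancy day was also set against the same 4 non-pregnant arrays, so the day comparisons share their controls and are not independent of one another. At day 3.5 (3 arrays) 9 genes were called, of which the microRNA genes Mir379 (0.74 ± 0.11, adjusted p = 0.00253), Mir539 (0.60), Mir376a (0.57) and the olfactory receptor Olfr1079 (0.53) were higher, and Krt77 (−0.56), Itga2b (−0.54), Palm3 (−0.52), Utf1 (−0.51) and A730049H05Rik (−0.49) were lower. The day 3.5 arrays had low acinar markers, with a mean of 6.78 against 8.61 in non-pregnant arrays and a list median of −2.11 (adjusted p = 3.83e-14, and adjusted p = 0.373 with an estimated correlation). The count of 9 was 0 with all 39 arrays in 1 model or with only these 2 groups (4046 genes had an unadjusted p under 0.05 in the limma model used here). It was 2 without day 3.5 replicate 1 or 2, 173, 5, 2 and 1 without non-pregnant replicates 1, 2, 3 and 4, and 321 with array weights.

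At day 6.5, 124 genes were called, 100 higher and 24 lower, or 105 and 65 after quantile normalization and 113 and 74 with the SD of each array as a covariate. Matn2 rose by 1.43 ± 0.13 (adjusted p = 1.96e-08), the DNA topoisomerase Top2a by 1.20 ± 0.16, the mitotic kinase Pbk by 0.98 and Tph2 by 0.93 ± 0.13, and the signalling regulator Rgs2 had the largest fall, −1.55 ± 0.27 (adjusted p = 0.00185), before the transcription factor Sox4 (−0.95). The cell cycle list rose, with 13 members higher (adjusted p = 0.00174 with an estimated correlation). The acinar list had a median of 0.85 (adjusted p = 0.00075, and adjusted p = 0.735 with an estimated correlation), which lost its call without non-pregnant replicate 3 (adjusted p = 0.375). The count was 221 and 48 without day 6.5 replicates 2 and 3, and 67, 75 and 78 without non-pregnant replicates 2, 3 and 4.

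At day 9.5, 3864 genes were called, of which 2321 were higher and 1543 lower, and 71 differed at least 2-fold (70 higher and 1 lower). Tph1 rose by 4.13 ± 0.22 (adjusted p = 5.91e-15), Cldn8 by 3.50 ± 0.18, Matn2 by 2.33, Tph2 by 2.30 and Top2a by 2.13 ± 0.16. Of the cell cycle list 33 members rose, with a median of 0.75 (adjusted p = 0.000513 with an estimated correlation), and Mki67 rose by 1.45. Genes of cholesterol synthesis rose in 9 of 17 cases, among them Dhcr7 (0.88), with adjusted p = 7.02e-08 for the list and adjusted p = 0.113 with an estimated correlation. Among called genes whose groups do not overlap, the largest falls were in Abca1 (−0.78), the microRNA genes Mir297b (−0.75) and Mir301b (−0.73), and Pcdh15 (−0.70); a covariate for the SD of each array ended the calls of Mir297b (adjusted p = 0.171) and Mir301b (adjusted p = 0.089). The acinar mean was 7.90 on these arrays against 8.61 in non-pregnant ones. This was the highest count among the pregnancy days, as were the 2347 after quantile normalization, but with the SD of each array as a covariate it was 627, below those of day 15.5 (2329), day 12.5 (1052) and day 18.5 (862). The split was 1314 higher and 1033 lower after quantile normalization, 466 and 161 with the SD covariate and 2504 and 764 with arrays centred on their medians. It was 2268 and 1973 without day 9.5 replicates 3 and 4, the latter below the 2210 of day 18.5, and 1930 without non-pregnant replicate 4.

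At day 12.5, 1051 genes were called, 813 higher and 238 lower, led by Tph1 (4.98 ± 0.22, adjusted p = 3.56e-17), Cldn8 (4.43) and Lrrc55 (3.13), with Rgs2 falling most (−2.05 ± 0.27, adjusted p = 2.42e-06). At day 15.5, 1641 were called, 737 higher and 904 lower, led by Tph1 (4.85), Cldn8 (4.68) and Lrrc55 (3.65), with Rgs2 at −2.38, Mdm1 at −1.25 and Sox4 at −1.20. At day 18.5, 2210 were called, 1712 higher and 498 lower, led by Cldn8 (5.0 ± 0.18, adjusted p = 1.13e-19), Tph1 (4.45) and Lrrc55 (4.28), Matn2 rose by 2.80 and Fbxw24 by 2.45 ± 0.18. The number of cell cycle genes that rose was 25 at day 12.5, 20 at day 15.5 and 11 at day 18.5, and the list held with an estimated correlation on days 12.5 and 15.5 (adjusted p = 0.000888 and 0.0225) but not on day 18.5 (adjusted p = 0.355). Mki67 rose by 0.93, 0.68 and 0.53 on these days, and its call at day 18.5 ended without day 18.5 replicate 4 (adjusted p = 0.0546, with 0.0048 to 0.202 over the alternatives). Of the protein folding list 10, 9 and 16 members rose, with Derl3 at 1.55 on day 18.5 (list adjusted p = 0.149, 0.297 and 0.146 with an estimated correlation). The serotonin list held on day 15.5 with 5 members higher (adjusted p = 0.0221 with an estimated correlation). The excess of higher genes at day 12.5 shrank to 766 against 510 lower after quantile normalization and to 592 against 460 with the SD covariate. The count at day 15.5 was 1015 with only these 2 groups fitted, and with arrays centred on their medians its split turned to 936 higher and 326 lower. That at day 18.5 was 1433 without day 18.5 replicate 4, and its excess of higher genes shrank to 1056 against 820 lower after quantile normalization and to 508 against 354 with the SD covariate.

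Over the 6 pregnancy days, 7940 genes differed from non-pregnant on at least 1 day by limma's F-test, and 7697 differed among the days. Among the latter, Cldn8 had the widest range of day means (5.38), then Tph1 (5.13) and Lrrc55 (4.41). The other 7 of the 10 widest were Reg2 (3.99) and digestive enzymes, among them Cpb1 (4.23), Try5 (4.16), Pnliprp1 (3.78) and Cel (3.75). The range of Cpb1 was 2.48 and that of Cel 2.45 without day 3.5 replicate 1, and with the acinar mean as a covariate, which is built in part from them, Cpb1 (adjusted p = 0.575), Pnliprp1 (0.165) and Cel (0.817) were not called. Try5 and Reg2, which are not in that mean, stayed called with it (adjusted p = 0.00165 and 0.00386), with ranges of 0.91 and 3.17.

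**Figure D2:**
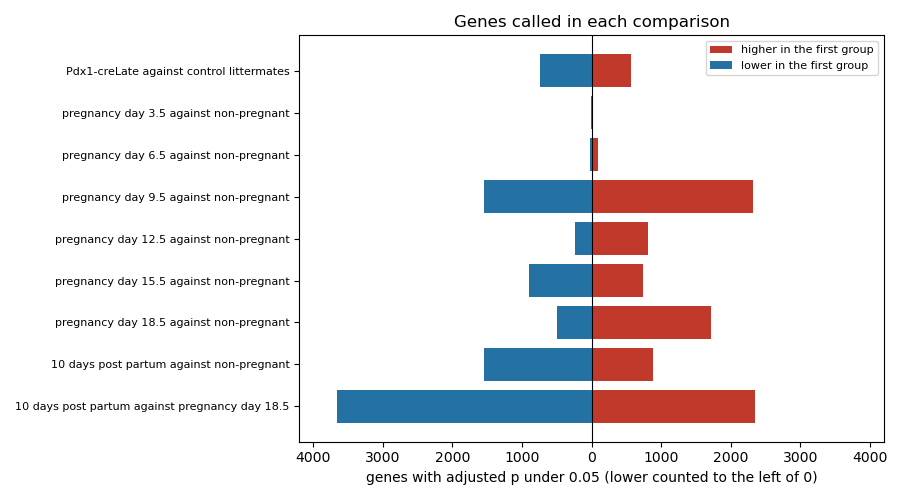
Number of genes with adjusted p under 0.05 in each comparison; bars to the right count genes higher in the group named before "against", bars to the left genes lower in it. Day 3.5 had 9 and day 9.5 had 3864.

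Islets at 10 days post partum were set against the same non-pregnant arrays to ask what differs after birth. The labels do not say whether these mice were nursing, so changes left from pregnancy cannot be told apart from those of lactation. Lrrc55 was higher by 4.35 ± 0.17 (adjusted p = 4.21e-18), Cldn8 by 3.90 ± 0.18, Tph1 by 3.45 ± 0.22 (adjusted p = 5.89e-13), Matn2 by 2.80 and Tph2 by 1.80. Gbp8 (1.73), Tnfrsf11b (1.63), Tmem255a (1.60), Lonrf3 (1.58) and Ivd (1.58) were also among the 10 largest rises. The largest falls were in Rgs2 (−1.63 ± 0.27, adjusted p = 9.98e-05), the imprinted gene Nnat (−1.25 ± 0.16, adjusted p = 2.47e-06), Pcdh15 (−1.18) and Mdm1 (−1.10). Endothelial markers fell: 6 of 16 were lower (10 adjusted over the list alone) and 0 higher, including Esam (−0.50, adjusted p = 2.72e-05), Kdr (−0.38) and Egfl7 (−0.38), with adjusted p = 1.3e-05 for the list and adjusted p = 0.291 with an estimated correlation. Of the fibroblast and stellate cell list 4 of 17 were lower, among them Acta2 (−0.88 ± 0.14) and Col3a1 (−0.63 ± 0.16), with adjusted p = 0.0052 and adjusted p = 0.522 with an estimated correlation. Of the clock genes 5 fell, with Cry2 at −0.73 and Per1 at −0.63 (list adjusted p = 0.00316, and adjusted p = 0.26 with an estimated correlation). Of the protein folding genes 11 were higher, with Derl3 at 0.80 (list adjusted p = 1.3e-05, and adjusted p = 0.48 with an estimated correlation), and Mki67 had 0.18. In all 2441 genes were called, 890 higher and 1551 lower. The count was 1541 without non-pregnant replicate 2 and 1220 with only these 2 groups fitted.

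The step across birth was measured as 10 days post partum against day 18.5, which shares no arrays with the mid-pregnancy comparison. Fbxw24 fell by 1.40 ± 0.18 (adjusted p = 2.41e-05), the neuropeptide Vip had −1.23 ± 0.32 (adjusted p = 0.0066), the synaptic vesicle gene Sv2b −1.15 ± 0.13 and Cldn8 −1.10 ± 0.18 (adjusted p = 0.000215). Tph1 had −1.0 ± 0.22 (adjusted p = 0.00204), Tph2 −0.55 (adjusted p = 0.00414), Socs2 −0.68 (adjusted p = 0.000281) and Ehhadh −0.93 ± 0.10 (adjusted p = 3.32e-06). The largest rises among called genes whose groups do not overlap were in Krtap5-1 (0.90 ± 0.16), Krtap5-2 (0.90), 4930505O20Rik (0.88), Olfr1200 (0.85) and Krtap5-4 (0.83), among which are keratin-associated proteins of hair and an olfactory receptor. Endothelial markers fell in 12 of 16 cases and rose in 1, with Plvap at −0.60, Eng at −0.55, Kdr at −0.53 and Esam at −0.50 (list adjusted p = 0.00036, and adjusted p = 0.371 with an estimated correlation). Lymphocyte markers were higher in 7 of 17 cases, with Cd3g at 0.45, Cd3d at 0.43 and Cd22 at 0.40 (list adjusted p = 0.00296, and adjusted p = 0.371 with an estimated correlation). The mean of this list was low, at 4.72 to 4.79 on the day 18.5 arrays and 4.86 to 5.02 post partum. Array medians lay between 5.8 and 6.0. After quantile normalization neither that list (adjusted p = 0.381) nor these 3 genes (adjusted p = 0.106, 0.0706 and 0.0931) were called.

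Across birth 6014 genes were called, 2355 higher and 3659 lower, of which 152 differed at least 1.5-fold and 8 at least 2-fold. The count was 1979 after quantile normalization, a nearly even split of 970 higher and 1009 lower. It was 24 with the SD of each array as a covariate, 3637 without day 18.5 replicate 4 and 3553 without post partum replicate 4. With the SD covariate Cldn8 (adjusted p = 0.128), Tph1 (0.163), Tph2 (0.297), Socs2 (0.292), Vip (0.647), Plvap (0.174), Eng (0.26), Kdr (0.223), Esam (0.0753) and the 5 rises named above from Krtap5-1 to Krtap5-4 (0.323 to 0.767) lost their calls. Array SD did not overlap between these groups (2.053 to 2.101 at day 18.5, 2.001 to 2.042 post partum). This covariate can thus widen the error and remove real differences too. A lost call does not show that a difference was absent. Of the 1340 genes higher in mid-pregnancy, 555 were lower after birth and 10 higher, against 246 and 158 expected from independent lists. After quantile normalization these were 162 and 24, against 67.8 and 65.2 expected. Of the 503 genes lower in mid-pregnancy, 132 were lower after birth and 22 higher (92.3 and 59.4 expected), but after quantile normalization 15 were lower and 29 higher (25.5 and 24.5 expected), so their direction depends on the scaling.

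The overlap of the transgene and mid-pregnancy calls asks whether the transgenic islets resemble islets of pregnancy, and these comparisons share no arrays. Sex-linked expression was male-like (low Xist, high Y-linked genes) in both groups of the transgene comparison and female-like in the C57bl6/J groups. The overlap thus sets a difference within males beside a difference within females. Tph1, Cldn8, Lrrc55, Matn2, Tph2, Tnfrsf11b, Cish and Socs2 were higher in both, and Tat was lower in both. Of the 571 genes higher in Pdx1-creLate, 310 were also higher in mid-pregnancy, against 38.4 expected (one-sided Fisher's exact test p = 1.09e-216 across genes, which are not independent replicates). Of the 742 lower ones, 167 were also lower, against 18.7 expected (Fisher's exact p = 8.31e-115). Another 7 genes were called in opposite directions. These shares were 54.3% of the higher and 22.5% of the lower genes. Across all genes Pearson's r between the log2 differences was 0.478 and Spearman's rho was 0.24. The lists of single days differ in length, so the genes higher and lower in both are given with those expected. They were 0 and 0 for day 3.5 (0.115 and 0.186 expected), 42 and 7 for day 6.5 (2.86 and 0.893), 319 and 93 for day 9.5 (66.5 and 57.4), 269 and 124 for day 12.5 (23.3 and 8.86), 261 and 223 for day 15.5 (21.1 and 33.6), 367 and 133 for day 18.5 (49 and 18.5) and 225 and 275 for 10 days post partum (25.5 and 57.7). Opposite calls numbered 35 at day 9.5, where Pearson's r was 0.248, and 3 at day 12.5, where it was 0.497.

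The difference between the transgene effect and the mid-pregnancy effect was tested as an interaction over all 39 arrays. The transgene effect was larger for Fbxw24 (3.81 ± 0.26), Cftr (3.47), Rerg (3.34), Adgrg6 (2.94) and Fmo1 (2.91), and for Tnfrsf11b (1.5) and Socs2 (1.13). It was lower for Dapl1 (−2.69 ± 0.22), Ugt2b34 (−2.48), Pdyn (−2.32), Prom1 (−1.93) and Taar1 (−1.61). Cell cycle genes set the comparisons apart: 23 of 37 had a lower transgene effect and 0 a higher one, with Top2a at −1.51 ± 0.21, Mki67 at −1.14 ± 0.18 and Bub1 at −1.13 ± 0.17, and a list median of −0.53 (adjusted p = 2.12e-27, and adjusted p = 0.00224 with an estimated correlation). The beta-cell identity list was also lower in the transgene effect, with 7 of 20 members called and a median of −0.26 (adjusted p = 1.07e-08, and adjusted p = 0.0282 with an estimated correlation), including Ucn3 (−0.88), Mafa (−0.73, adjusted p = 0.00123), Foxa2 (−0.58) and Slc2a2 (−0.43). The STAT5 list was higher (3 members, adjusted p = 0.0349 with an estimated correlation). Tph1 (0.75, adjusted p = 0.391), Tph2 (0.49, adjusted p = 0.105) and Cish (0.78, adjusted p = 0.287) did not differ by this test. Tph1 became called without control replicate 4 (1.43, adjusted p = 0.000915) and Cish without control replicate 3 (1.23, adjusted p = 0.0178), while over all 35 alternatives the adjusted p reached 0.63 for Tph1 and 0.632 for Cish. In all 1093 genes were called, 324 with a higher and 769 with a lower transgene effect. The arms of this contrast also differ in sex-linked expression, with mean Xist at 4.25 and 4.38 in the transgene arm and 9.85 or more in the C57bl6/J groups.

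**Figure D3:**
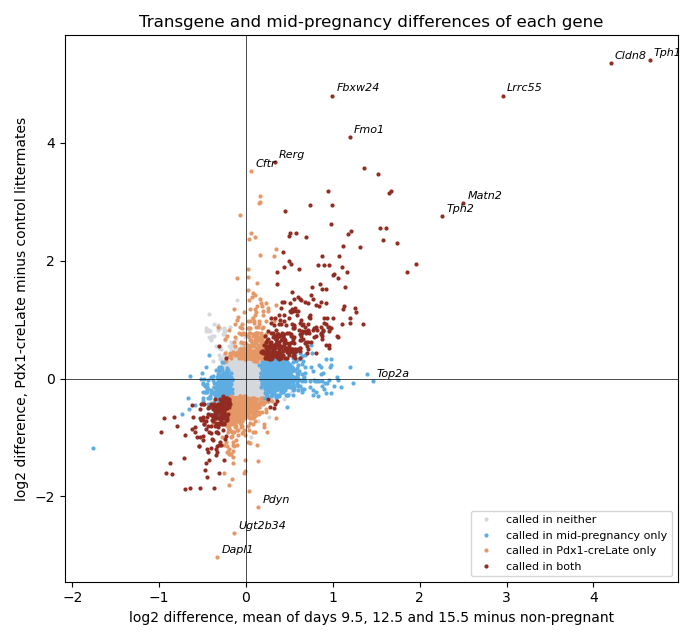
Log2 difference of each gene in mid-pregnancy minus non-pregnant islets (horizontal) and in Pdx1-creLate minus control islets (vertical), coloured by the comparison in which it was called. Tph1 lies at 4.65 and 5.40, while Top2a lies at 1.46 in mid-pregnancy near 0 on the vertical axis.

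**Figure D4:**
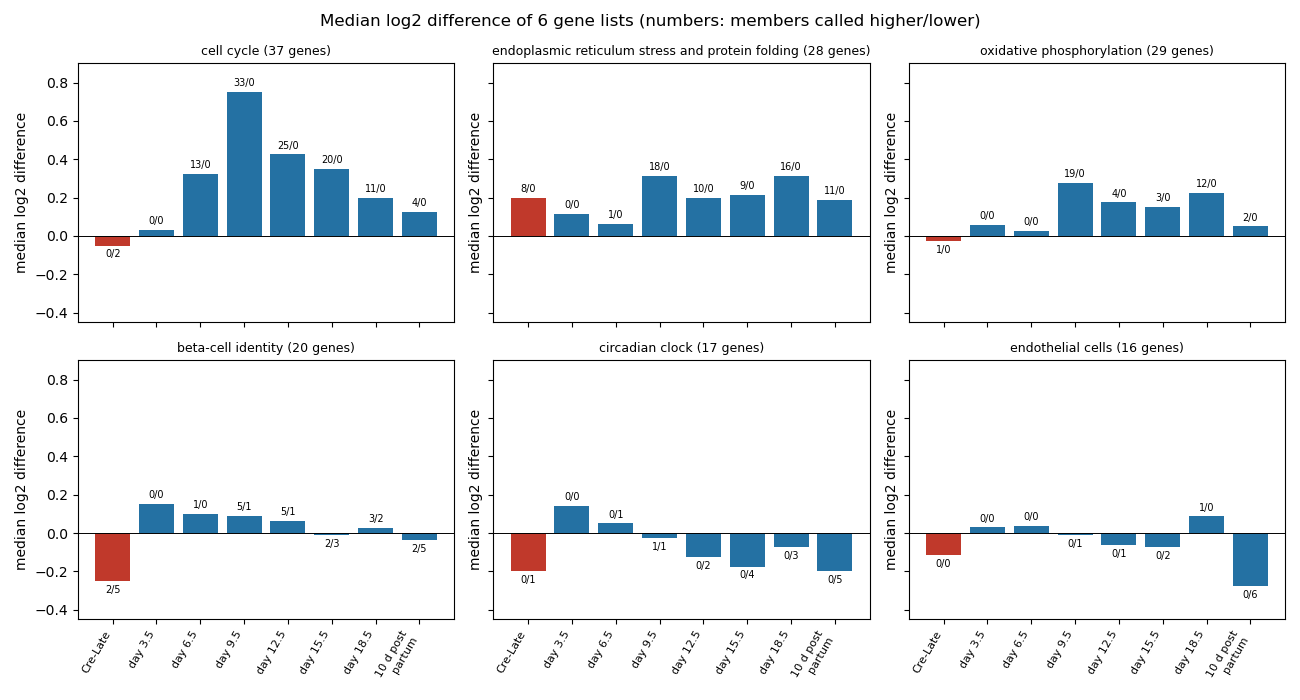
Median log2 difference of the measured members of 6 gene lists in Pdx1-creLate against control littermates (red) and in each pregnancy day and 10 days post partum against non-pregnant (blue), with the members called higher and lower printed at each bar. The cell cycle list peaks at 0.75 on day 9.5 and lies at −0.05 in Pdx1-creLate.

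Control littermates and non-pregnant C57bl6/J mice, both wild type and not pregnant, were compared to measure how far the arms of the study differ by themselves. Xist, which is expressed from the inactive X chromosome, was lower in control littermates, at −5.90 ± 0.14 (adjusted p = 3.56e-30), and the Y-linked genes Eif2s3y, Uty and Kdm5d were higher by 4.70 ± 0.10, 4.63 ± 0.09 and 2.83 ± 0.12. Mean Xist was 4.25 in Pdx1-creLate and 4.38 in control littermates and between 9.85 and 10.47 in the other 8 groups, while Uty was 8.28 and 7.82 against 3.00 to 3.20. Of the 7 genes of the delta-cell list 4 were lower, among them the imprinted gene Nnat (−1.0), Rbp4 (−0.80) and the hormone Sst (−0.48). The list had adjusted p = 0.000508 by camera and adjusted p = 0.0804 with an estimated correlation, and it was not tested without Nnat. Genes of branched-chain amino acid breakdown were higher in 10 of 18 cases, with Auh at 0.63 and Acad8 at 0.58 (list adjusted p = 1.61e-06, and adjusted p = 0.137 with an estimated correlation), and protein folding genes in 13 of 28, with Derl3 at 0.98 and Sdf2l1 at 0.88 (adjusted p = 8.49e-06, and adjusted p = 0.374 with an estimated correlation). In control littermates against non-pregnant mice 3994 genes were called, 2607 higher and 1387 lower, and 7849 were called with every probe set tested on its own. The excess of higher genes depends on the scaling, with 2134 higher and 2094 lower after quantile normalization and 1757 and 1463 with arrays centred on their medians. Sex, strain background and any difference in handling separate the same arrays here and cannot be told apart.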

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

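The tests of exocrine tissue and of a fading response across birth, of a weaker response in 1 control animal and of a lower share of beta cells were chosen only after the results were seen, as were the array SD covariate and the allowance for rounding in the test for outlying arrays.

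Control littermate replicate 4 had Tph1 at 7.3 against 4.5 to 4.6 in the other controls, Cldn8 at 7.9 against 5.1 to 5.3, and Pcp4 at 7.5 against 8.8 to 8.9. A wrong genotype label is argued against, because over 13 genes at least 8-fold higher in Pdx1-creLate the array stood at 0.204 of the way from controls to Pdx1-creLate. A weaker transgene-like response is argued against for the falling genes, since 69 genes at least 2-fold lower in Pdx1-creLate had a median of 0.00 on this array where −0.25 was predicted from its position and the other controls had −0.05 to 0.05. An admixture of Pdx1-creLate RNA may account for some of the rises: a share of 8.37%, set from Tph1, predicted a median excess of 0.97 over the 13 genes and 0.60 was seen, and 9 of them came closer to the prediction than to no excess. It leaves out Cftr (−0.03 against 0.96 predicted, SD 0.23 in the other controls), Adgrg6 (0.03 against 0.76, SD 0.15), Pcp4 (−1.33 against −0.09) and Rgs2 (−1.70 against −0.08), so a separate state of this animal stays open.

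Of 20 beta-cell identity genes 5 were called lower in Pdx1-creLate and 2 higher, and the list was not called with an estimated correlation (limma camera adjusted p = 0.291). Exocrine tissue as the whole source is argued against, since 4 of the 5 stayed called with the acinar mean as a covariate; Mafa went from −0.38 ± 0.10 to −0.33 ± 0.11 (adjusted p from 0.0283 to 0.106, with 0.00782 to 0.166 over all alternatives), a call lost to a smaller difference with a larger error. A wider spread of the arrays is argued against in that 5 of 5 stayed called after quantile normalization. A lower share of beta cells would raise the markers of other islet cells. Of 19 genes on their lists, however, 7 were called lower, among them the imprinted gene Nnat, and 2 higher. These were counted without the acinar covariate, and the acinar mean was 9.11 in Pdx1-creLate against 8.49 in controls. Exocrine tissue could thus hide such a rise, and the count does not decide on the share of beta cells. This test replaced one on Pdx1 (0.05) and Nkx6-1 (−0.43) after that had been seen. A lower level of these 5 genes within beta cells is a hypothesis left open, found and tested on the same arrays.

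The step from day 18.5 to 10 days post partum gave 6014 called genes with small differences. Exocrine tissue is argued against, since 5814 genes were called with the acinar covariate. A difference in the spread of the arrays could contribute: the mean array SD was 2.09 at day 18.5 and 2.01 post partum, and across genes the slope on array SD within the other 8 groups correlated with the step across birth at r = −0.628 (−0.638 to −0.571 with each array left out), genes not being independent replicates. Array SD is made from the same values and was already known to differ between these groups, which by itself favours a negative r. The correlation thus does not tell whether the spread has a technical or a biological source. A fading of the rises of pregnancy may be present as well, since 45 genes at least 2-fold higher in mid-pregnancy had a quantile-normalized median of −0.375, and the lowest median among 10000 random lists was −0.12. With the array SD as a covariate, the 1340 genes called higher in mid-pregnancy had a median of −0.041. Of them 8 were called lower and 0 higher across birth (1.08 and 0.538 expected). For the 503 genes lower in mid-pregnancy the scaling decides, with 132 lower and 22 higher across birth (92.3 and 59.4 expected from independent lists) but 15 and 29 after quantile normalization (25.5 and 24.5 expected), so the spread of the arrays and a fading, seen in the rises alone, stay open.

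Outlying arrays were looked for in 609 gene and group pairs and 27 array measures with Dixon's ratio, where chance marks about 1 in 20. On the rounded values 77 pairs (12.6%) passed and 8 (1.31%) did so whatever the rounding hid. Besides the control array above, Etv1 was 6.8 in Pdx1-creLate replicate 4 (7.5 in the others) and Ttr was 11 there (11.7 in the others). Non-pregnant replicate 1 had Ins2 at 11.9 (12.7 in the others), Sst at 12.9 (13.7) and its highest value at 13.3 (14.4 or more). Reg2 was 5.0 in day 18.5 replicate 4 (7.9 to 8.0), whose acinar mean was 8.11 (9.14 to 9.34), and the acinar mean was 7.38 in non-pregnant replicate 3 (8.90 to 9.18). The array SD was 1.98 in day 15.5 replicate 2 (2.04 to 2.05) and 2.04 in post partum replicate 3 (2.00 to 2.01).

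Some effects differed between arms or times by a test of the difference itself. Among the pregnancy days 7697 genes differed, and 1093 genes had a transgene effect unlike the mid-pregnancy effect. In that contrast the cell cycle list had a median of −0.53 and the beta-cell identity list −0.26. The log2 differences were 3.81 for Fbxw24, 3.47 for Cftr, 3.34 for Rerg, 2.94 for Adgrg6, 2.91 for Fmo1, 1.5 for Tnfrsf11b, 1.13 for Socs2 and 0.58 for the growth factor receptor Igf1r. They were −2.69 for Dapl1, −2.48 for Ugt2b34, −2.32 for Pdyn, −1.93 for Prom1, −1.61 for Taar1, −1.51 for Top2a, −1.14 for Mki67, −1.13 for Bub1, −0.88 for Ucn3, −0.73 for Mafa, −0.58 for Foxa2 and −0.43 for Slc2a2.

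The 13767 probe sets without a single gene symbol were used in no comparison above. Tested by themselves, 27 were called in Pdx1-creLate (18 higher, 9 lower, largest rise 3.03) and 152 in mid-pregnancy (127 higher, 25 lower, largest rise 1.26).

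Other splits of the same arrays were fitted to see whether a grouping by chance gives as many called genes. The real split gave the highest count for Pdx1-creLate (1313, highest other 0), day 6.5 (124, 12), day 9.5 (3864, 522), day 12.5 (1051, 5), day 15.5 (1641, 71) and day 18.5 (2210, 5). The same held for 10 days post partum (2441, 2193), any day (7940, 309), differences among days (7697, 503), the step across birth (6014, 2507) and control littermates against non-pregnant (3994, 63). Comparisons of a pair of groups had only 35 splits, and no adjustment over comparisons was made. Other splits also called many genes for 10 days post partum and across birth. These ranks thus argue against chance without excluding it. For mid-pregnancy (1843, 2840) and for the interaction (1093, 1165), 1 other split of 100 gave a higher count than the real one. The real split thus ranked 2 of 100, which also argues against chance without excluding it. These splits exchanged arrays among days 9.5, 12.5 and 15.5 and non-pregnant, so they can pick up differences among days. For the overlap (477, highest other 0) nothing is added, since the other splits of the transgene arrays called 0 genes and could share none. Chance cannot be excluded for day 3.5, where 9 genes were called and another split gave 50, several times as many. The source of that larger count was not tested.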

How the results depend on the processing

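The array SD covariate and the rounding noise were chosen only after the data were seen. That covariate is made from the same values and does not overlap between day 18.5 and 10 days post partum, so it can remove real differences there. Leaving out each array in turn, the called genes ranged over 957–1175 for Pdx1-creLate, 1–173 for day 3.5, 48–221 for day 6.5, 1930–4587 for day 9.5, 786–961 for day 12.5, 1131–1865 for day 15.5, 1433–2504 for day 18.5, 1541–3004 for 10 days post partum, 1390–1998 for mid-pregnancy, 6535–8149 for any day, 6025–8040 among days, 3553–7116 across birth, 811–1147 for the interaction, 2972–3586 for control littermates against non-pregnant, 391–486 for the overlap and 96–106 for called lists. The lowest and highest came without Pdx1-creLate replicates 3 and 2 for the transgene and without non-pregnant replicates 4 and 1 for day 3.5. Day 3.5 had 9 genes, with 4 after leaving out the dimmest 25% of genes, 15 after quantile normalization, 21 with trended and robust eBayes, 321 with array weights, 3 with the acinar covariate, 5 with the replicate block, and 0 in 1 model of 39 arrays or with only 2 groups. Quantile normalization gave 2347 for day 9.5, 5099 among days and 1979 across birth. The array SD covariate gave 768 for Pdx1-creLate, 187 for day 6.5, 627 for day 9.5, 862 for day 18.5, 4844 for any day, 4910 among days and 24 across birth. All probe sets gave 820 for Pdx1-creLate and 7849 for control littermates against non-pregnant, all 39 arrays in 1 model 2484 for Pdx1-creLate, and only the 2 groups 45 for day 6.5, 1015 for day 15.5 and 1220 for 10 days post partum. The overlap was 0 with day 3.5 and 49 with day 6.5 in place of mid-pregnancy, and 12 list calls held with an estimated correlation.

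Some directions turned over. In Pdx1-creLate, Ins2 had 0.039 after quantile normalization, Prl 0.028 and Men1 −0.069 with the SD covariate, and with arrays left out Men1 ranged from −0.042 (without control replicate 1) to 0.067, below 0 also without Pdx1-creLate replicate 4 (−0.033), and Pdx1 from −0.008 (without control replicate 1) to 0.092. In mid-pregnancy Ins2 ranged from −0.008 (without non-pregnant replicate 1) to 0.258, and across birth Ccr7 had −0.134 with the SD covariate. List medians were 0.042 at day 3.5 for acinar cells with the acinar covariate, which is built from that list, −0.033 for beta-cell identity at day 9.5 after quantile normalization, and across birth with the SD covariate 0.028 for protein folding, 0.002 for branched-chain amino acid breakdown and 0.039 for oxidative phosphorylation. At day 6.5 the acinar median shrank to 0.004 with the acinar covariate and kept its sign, while the direction of the list's test turned. Except where fewer genes or arrays were used by construction, the cause was not tested. Of the results of named genes, 38 lost their call with the SD covariate, 14 with quantile normalization, 18 with all probe sets, 15 with the acinar covariate and 10 with the block, and of 3324 results with an array left out 108 did. Signal over background limits what can be seen of dim genes.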

Other observations

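The imprinted gene test was chosen only after the results were seen. Of 18 genes of branched-chain amino acid metabolism, 2 rose in Pdx1-creLate islets: Ivd by 1.95 ± 0.13 (adjusted p = 1.86e-07) and Bcat1, the cytosolic transaminase, by 1.33 ± 0.14 (adjusted p = 2.02e-05), with 4 arrays per group, while the other 16 were not called, the list median was −0.08 and the list was not called (adjusted p = 0.538). Among 12 ductal markers Cftr and the keratin Krt18 (0.48, adjusted p = 0.00818, or 0.104 with the array SD covariate) were higher and Prom1 was lower, and the list was not called (adjusted p = 0.831). Among 8 alpha-cell markers Sh3gl2 rose (1.15 ± 0.09) while Dpp10 (−1.05 ± 0.15) and the transport protein Ttr (−0.95 ± 0.16) fell, and Gcg had −0.20 (adjusted p = 0.257). In mid-pregnancy Sh3gl2 (0.58) and Krt18 (0.58) rose too.

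Of 21 macrophage and dendritic cell markers, only C1qa, a chain of complement C1q, was called in mid-pregnancy (0.93 ± 0.09, adjusted p = 8.17e-09), and the list was not (adjusted p = 0.867). Of 22 genes of interferon response and antigen presentation, 8 rose at day 9.5 (10 adjusted over the list alone), with adjusted p = 5.4e-05 for the list and adjusted p = 0.375 with an estimated correlation. Of these genes 0 rose and 1 fell 10 days post partum (adjusted p = 0.501). Between control littermates and non-pregnant mice, 4 of 8 alpha-cell markers were lower, among them Dpp10 (−0.58), with adjusted p = 0.00113 for the list and adjusted p = 0.256 with an estimated correlation.

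The falls of Nnat and Zim1 raised the hypothesis that imprinted genes may move as a set. Of 34 measured, 13 were lower and 2 higher 10 days post partum, with adjusted p = 0.00653 and adjusted p = 0.179 with an estimated correlation. Without Nnat and Zim1 the adjusted p was 0.0581, and 0.306 with an estimated correlation, so the set passed by neither setting once the genes that raised the hypothesis were left out. An adjusted p of 0.05 or more had been set to exclude a change of the set; that reading was given up after the result was seen, because a missed threshold does not show that genes did not move. A change of imprinted genes as a set was thus not shown, and it is not excluded.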
